A study of Homo sapiens with 45 samples.

How the data were processed

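Poly(A) RNA of 4 human T-ALL lines was sequenced in 45 libraries, 3 per group. Jurkat RNA went through a Maxwell extraction and a non-directional NEBNext Ultra II kit, and RNA of the 3 other lines through RNeasy columns and a directional kit. In Jurkat libraries reads of overlapping genes on opposite strands could therefore not be told apart. Guide-transduced Jurkat cells had puromycin for 4 days and were collected on day 10. Labels name each library as a biological replicate.

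Per the labels, the authors aligned reads with HISAT2 2.2.1 to hg38, counted them per gene with featureCounts 2.0.3 and tested them with DESeq2 1.38.2. DESeq2 output was not used here. The authors deposited TPM (transcripts per 1e+06) in 2 tables of 38557 genes, 1 for Jurkat and 1 for the other lines, and each deposited table also gives a gene length in bases per gene. Each library totalled 1e+06 TPM, so a large change in a few abundant genes shifts all others. TPM times gene length, divided by a step found per library, gave whole numbers within 0.01 for 100% of genes above 0, and these were taken as reads. By this measure depth was 29.7 to 47.9 M reads in Jurkat and 19.7 to 27 M in the other lines. Mitochondrially encoded mRNAs took 20 to 24.9% of TPM in Jurkat and 4.99 to 8.04% in the other lines. Group means of depth were 33.1 ± 2.16 M for BRM014 and 35.5 ± 1.21 M for DMSO at 6 h, 36.9 ± 3.4 M and 34.8 ± 2.05 M at 8 d, 39.2 ± 9.15 M in gAAVS1, 43.5 ± 3.45 M in gARID1A, 43.4 ± 2.62 M in gARID1A_1B, 37.3 ± 4.27 M in gSMARCA4 and 42 ± 4.01 M in gSMARCA4_A2. No 2 replicates were identical or within counting noise of each other, with a chi-square per degree of freedom between 2.59 and 48. Gene positions on hg38 were joined by symbol, which matched 34951 genes, or 35645 with synonyms.

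Genes with at least 1 TPM in at least 3 libraries of a table were tested, 17936 in Jurkat and 16241 in the other lines. Differences were fitted on log2(TPM + 1) with limma 3.58.1 (lmFit, contrasts, eBayes with an intensity trend and robust) in R 4.3.3, with all groups of a table in 1 fit, which left 18 and 12 residual degrees of freedom. The Benjamini-Hochberg adjusted p threshold was 0.05. There were 9 comparisons with a control, 2 comparisons of a group with 2 targets against the group with 1, and 4 differences between 2 effects fitted as contrasts. Differences between Jurkat and the other lines were not fitted, since table and kit differ along with the line. A table of 24 gene lists was tested with camera at a correlation of 0.01 between genes, with camera at a correlation estimated from the data, and with fry. Members of each list were also adjusted over the list alone. Correlations of effects are Pearson's and Spearman's across genes. Effects that share the gAAVS1 libraries were set beside 20 simulations of unchanged genes with a shared control. Figures were drawn in Python 3.11.15.

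Tests, lists, alternatives and the rule for named genes were chosen before the data were examined, except limma-voom on the recovered reads and the removal of CCRF-CEM replicate 3 from both groups, which were added after, and the tests that weigh explanations in the closing section, which were chosen after their patterns were seen. Genes were named by this rule. For BRM014 in Jurkat at 6 h and 8 d, gARID1A_1B and gSMARCA4_A2, the 6 largest increases and 6 largest decreases were taken among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and every treated library beyond every control library. In the other comparisons and in the differences between effects 3 of each were taken. For genes called in all 4 lines it was up to 6 of each. From each list up to 3 members with the largest change at an adjusted p under 0.05 were taken, and always ARID1A, ARID1B, SMARCA4, SMARCA2, TAL1, GATA3, RUNX1, MYB, MYC, NOTCH1, NOTCH3 and BCL2. A few genes that the rule names are not reported.

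Alternatives were a pseudocount of 0.1, no filter on low values, a filter of 5 TPM, median-ratio rescaling of the libraries, mitochondrial genes left out with TPM rescaled, eBayes without trend and not robust, only the groups of the comparison in the fit, the replicate number as a block, a fold threshold of at least 1 on the log2 scale, each library left out in turn, and the 2 added later. Where a group was left with 2 libraries the pooled spread of the fit was used. Whether replicate numbers pair the libraries was checked from the correlation of departures from the group means, with a threshold of 0.1 for every pair. CCRF-CEM passed with 0.12, 0.29 and 0.45. The lowest correlation was 0.04 in KOPT-K1, 0.03 in TALL-1, 0.09 and -0.08 in Jurkat at 6 h and 8 d, and between -0.01 and 0.03 in the guide comparisons. In KOPT-K1, TALL-1, Jurkat at 6 h and gARID1A_1B all 3 numbers still correlated best with their own number, as in CCRF-CEM. Weaker pairing was therefore not excluded there. The main fit used no block in any comparison. The lowest p an exact permutation test can give with 3 against 3 is 0.1, so single values rest on limma. The pipeline was tested on simulated data with the depth and control levels of 2 comparisons. Every gene had the same spread, the median over well-read genes in the groups of the table. Changed genes were drawn only from those above a floor of expected reads, so the pipeline was not tested on changed genes with fewer reads. Of genes changed by 0.32 on the log2 scale it recovered 28% in the setting of CCRF-CEM and 36% in that of gSMARCA4_A2, so many changes of that size go uncalled. Of genes changed 1.5-fold it recovered 81.6% and 86%, and of those changed 2-fold 100% in both, with 7 unchanged genes called of 14846 tested and 3 of 17201. Camera called the list shifted in each simulation and left the unshifted list uncalled. Genes were simulated independently, so this does not test camera on lists whose members are correlated.

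Genes that share reads, among them histone genes, zinc finger genes, copies of ribosomal RNA and read-through genes such as FXYD6-FXYD2 and GIMAP1-GIMAP5, have uncertain individual values. Protein, cell number and viability were not measured in these files, so no statement on growth was made. Nothing among the 45 libraries was left out of the tests.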

Results

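Messenger RNA was measured by RNA-seq in 45 libraries from 4 human T-cell acute lymphoblastic leukaemia lines, in 15 groups of 3 libraries each. Jurkat cells gave 9 groups. In 5 of them, CRISPR guides were aimed at the AAVS1 site (gAAVS1, the control), at ARID1A (gARID1A), at ARID1A and ARID1B (gARID1A_1B), at SMARCA4 (gSMARCA4), or at SMARCA4 and SMARCA2 (gSMARCA4_A2), and RNA was taken 10 days after transduction. The other 4 Jurkat groups received 1 uM BRM014, which blocks the ATPase activity of SMARCA4 and SMARCA2, or 0.01% DMSO, for 6 h or 8 d. The lines TALL-1, KOPT-K1 and CCRF-CEM each received BRM014 or DMSO for 6 h. ARID1A, ARID1B, SMARCA4 and SMARCA2 encode subunits of cBAF, a complex that moves nucleosomes and opens regulatory DNA. Jurkat libraries held 29.7 to 47.9 M reads on genes, and libraries of the other lines 19.7 to 27 M, so counting error was small for genes above a few TPM (transcripts per 1e+06). Errors beside log2 fold changes are standard errors from limma, and those beside TPM are SD with n = 3. Each call is at an adjusted p under 0.05. In each called gene named here all 3 treated libraries lay beyond all 3 control libraries, unless a smaller number is given, a separation that 1 of the 10 possible splits of 6 libraries gives by chance.

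The first comparison asked whether the guides lowered the mRNA of their targets. SMARCA4 (chromosome 19, 10961030 to 11062273, hg38) fell to 44.2 ± 1.63 TPM in gSMARCA4 from 95.5 to 100 TPM in the 3 gAAVS1 libraries, a log2 fold change of -1.12 ± 0.06 (adjusted p = 1.6e-12), and to 49.9 ± 2.35 TPM in gSMARCA4_A2 (-0.95, adjusted p = 8.7e-12). ARID1B (chromosome 6, 156776026 to 157210779) fell to 11.9 ± 0.993 TPM in gARID1A_1B from 22.7 ± 0.525 TPM (-0.88, adjusted p = 5.5e-11). ARID1A (chromosome 1, 26696015 to 26782104) fell by 0.18 in gARID1A, from 94.4 ± 0.697 to 83.1 ± 3.38 TPM (adjusted p = 0.0073). In gARID1A_1B its change was 0.10 and was not called (adjusted p = 0.096), and it was called higher at 0.13 after rescaling of the libraries by their median ratio or with the mitochondrial genes left out. SMARCA2 (chromosome 9, 2015347 to 2193620) stood at 22.4 ± 0.288 TPM in gSMARCA4_A2 and 21.8 ± 0.931 TPM in gAAVS1 (0.04, adjusted p = 0.67). A guide can disrupt a protein without lowering its mRNA, and protein was not measured. ARID1A mRNA rose in the groups given guides against SMARCA4 or BRM014, by 0.40 in gSMARCA4, 0.70 in gSMARCA4_A2, 0.37 after BRM014 at 6 h and 0.64 at 8 d.

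**Figure D1:**
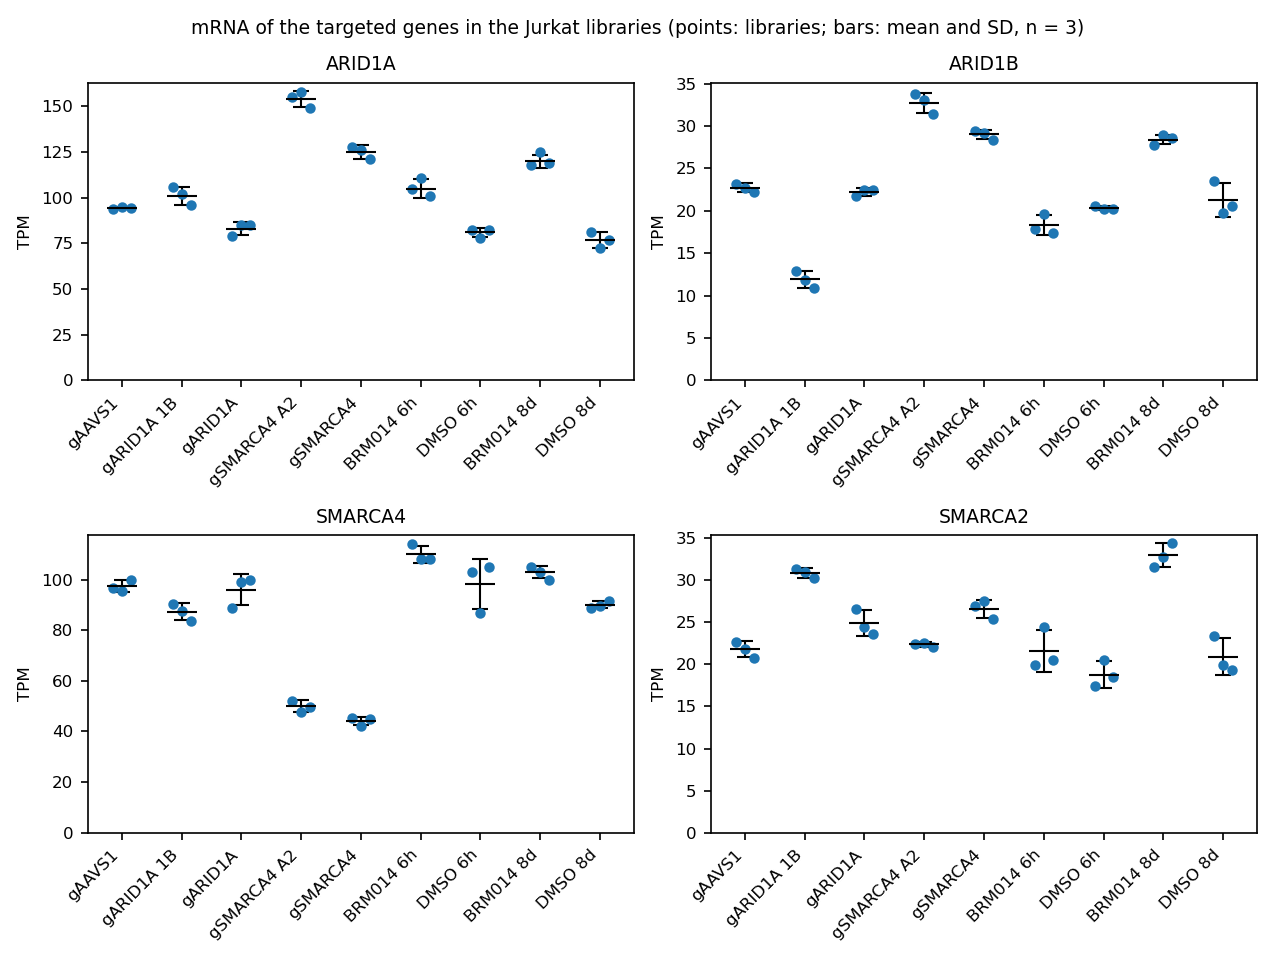
TPM (vertical axis) of ARID1A, ARID1B, SMARCA4 and SMARCA2 in the 9 Jurkat groups; points are libraries and bars the mean and SD of 3. SMARCA4 stood at 44.2 TPM in gSMARCA4 and 95.5 to 100 TPM in gAAVS1, while SMARCA2 stood at 22.4 TPM in gSMARCA4_A2 and 21.8 TPM in gAAVS1.

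BRM014 for 6 h in Jurkat asked which mRNAs respond early to an inhibitor of SMARCA4 and SMARCA2, the ATPases of cBAF and of related complexes. SASH3, an adaptor of lymphocyte receptor signalling (chromosome X, 129779949 to 129795201), fell from 132 ± 10.5 to 21.4 ± 0.927 TPM (log2 fold change -2.57 ± 0.07, adjusted p = 8.7e-17). SYT11, a regulator of vesicle release (chromosome 1, 155859567 to 155885199), rose to 20.1 ± 1.19 TPM (3.23 ± 0.08, adjusted p = 3.5e-17). TCF7, a transcription factor that sets T-lineage identity (chromosome 5, 134108218 to 134148210), fell from 25.8 ± 2.3 to 4.18 ± 0.578 TPM (-2.38 ± 0.08, adjusted p = 3e-15), and the T-lineage factor BCL11B fell by 1.72. The other large decreases were in PLA2G3 (-3.02), SLA (-2.74), CD48 (-2.63), KCNA6 (-2.56) and GIMAP2 (-2.49), and the other large increases in TRIB1 (2.51), CCDC121 (2.11), CTTN (1.8), CCDC96 (1.74) and RHEBL1 (1.61). Among the drivers of T-ALL, TAL1 fell by 0.42, GATA3 by 0.73, MYB by 0.78, MYC by 0.94, NOTCH1 by 0.78 and NOTCH3 by 1.49, and BCL2 was not called (-0.28, and called at -0.31 after median-ratio rescaling). Of 17936 genes tested, 8509 were called, 4801 higher and 3708 lower. At a change of at least 2-fold, 94 were higher and 276 lower.

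At 6 h the T cell receptor and T cell identity list had 0 of 29 members higher, 25 lower and 4 not called (0 and 26 adjusted over the list alone), with a median of -0.78. CD6 fell by 2.01, SH2D1A by 1.66 and LAT by 1.46. The list passed camera at an adjusted p = 1.9e-13, and had an adjusted p = 0.062 with an estimated correlation. Glycolysis and hypoxia genes had 17 of 22 lower and 0 higher (17 adjusted over the list alone, median -0.35, 1.1e-06, and 0.062 with an estimated correlation), among them ENO2 (-0.85) and HK1 (-0.68). T-ALL transcription factors had 4 higher and 15 lower of 25 (4 and 16 adjusted over the list alone, median -0.42, 4.9e-05, and 0.28 with an estimated correlation). NOTCH1 target genes had 2 higher and 7 lower of 15 (median -0.20), with DTX1 at -1.24 and IL7R at -1.27. Genes of MYC and ribosome biogenesis had 0 higher and 12 lower of 28 (median -0.19), and apoptosis regulators 1 higher and 7 lower of 15 (median -0.20). These 3 lists passed camera at adjusted p = 0.0097, 0.0011 and 0.036, against 0.23, 0.68 and 0.28 with an estimated correlation. Cholesterol synthesis genes were higher, 11 of 21 with 0 lower (12 adjusted over the list alone, median 0.34, adjusted p = 0.0084, and 0.68 with an estimated correlation), with SC5D at 0.95 and MVK at 0.94. Without BRM014 replicate 2 this list had a median of 0.20 and an adjusted p of 0.052. The apoptosis list lost its call after median-ratio rescaling (0.057).

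Lists not called at 6 h included cell cycle (15 higher and 1 lower of 31, median 0.14, adjusted p = 0.093), TAL1-complex target genes (4 and 8 of 15, -0.37, 0.076), immediate early and AP-1 genes (2 and 6 of 22, -0.14, 0.05 as rounded) and the integrated stress response (1 and 5 of 20, -0.14, 0.093). cBAF subunits had a median of 0.05 with 8 higher and 3 lower of 20, interferon response genes -0.15 with 5 and 7 of 19, and heat shock genes -0.15 with 1 and 2 of 12. PBAF and ncBAF subunits had 3 higher and 3 lower of 7, a median of -0.06 and a mean of 0.14. p53 targets had 6 higher and 3 lower of 18, a median of -0.01 and a mean of 0.10, and NF-kB targets 3 and 4 of 11, a median of -0.08 and a mean of 0.02, so that median and mean differed in sign in these 3 lists. As measures of library quality, the 13 mitochondrially encoded mRNAs had a median of 0.02, which was -0.02 after median-ratio rescaling, the 28 cytosolic ribosomal proteins 0.05 and the 11 replication-dependent histones of the 32 listed 0.29. Marker lists of other cell types were mostly below the filter. Of B cell markers 2 of 10 could be tested (median -0.67), of myeloid markers 2 of 14 (0.18), of erythroid and megakaryocyte markers 4 of 14 (-0.03), and of epithelial and fibroblast markers 4 of 12 (-0.45, adjusted p = 0.028, and 0.28 with an estimated correlation). The last call was absent without DMSO replicate 2 (0.071).

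BRM014 for 8 d in Jurkat asked what follows lasting inhibition. EEF1A2, a translation elongation factor normally of nerve and muscle (chromosome 20, 63488014 to 63499083), rose from 0.322 ± 0.0523 to 28.3 ± 2.38 TPM (4.47 ± 0.13, adjusted p = 2.4e-17). CXCR4, the chemokine receptor that guides leukaemia cells to marrow (chromosome 2, 136114349 to 136118149), fell from 253 ± 42.5 to 12.6 ± 0.66 TPM (-4.21 ± 0.11, adjusted p = 1.7e-17). TRIB1 (4.19), CTHRC1 (4.17), HEY1 (3.90), CCR4 (3.65) and SOSTDC1 (3.41) rose, and PLA2G3 (-4.82), TRAT1 (-4.11), MZB1 (-4.07), CD6 (-3.78) and FXYD2 (-3.77) fell. TCF7 stayed low, at 2.19 ± 0.264 TPM against 11.7 ± 0.852 TPM in DMSO (-1.99). TAL1 was higher by 1.26 and NOTCH1 by 0.33, while MYC (-0.93) and NOTCH3 (-1.43) were lower. GATA3 was higher by 0.32 in 2 of 3 libraries beyond all controls (adjusted p = 0.035), a call that median-ratio rescaling ended. In all, 10739 genes were called, 6612 higher and 4127 lower, and 722 and 383 of them by at least 2-fold. After median-ratio rescaling the split was 5504 higher and 5307 lower, and with a replicate block 4698 higher and 2704 lower.

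Cholesterol synthesis was the list with the largest median decrease among those of more than 2 genes at 8 d, with 20 of 21 members lower and 1 higher (the same counts adjusted over the list alone, median -1.17, adjusted p = 2.3e-08, and 0.38 with an estimated correlation). HMGCS1, which makes the precursor of sterols, fell from 567 ± 42.3 to 145 ± 9.39 TPM (-1.96 ± 0.26, adjusted p = 1.5e-06), and LSS (-1.64) and MSMO1 (-1.60) fell. Cell cycle genes were lower in 22 of 31 with 0 higher (22 adjusted over the list alone, median -0.32, 4.2e-08, and 0.095 with an estimated correlation), CDC6 by -0.93 and CENPF by -0.67. Glycolysis and hypoxia genes had 1 higher and 17 lower of 22 (median -0.28, 7.4e-06, and 0.095 with an estimated correlation), with VEGFA at -2.21. Cytosolic ribosomal proteins had 1 higher and 20 lower of 28 (median -0.15, 8.5e-06, and 0.38 with an estimated correlation). NF-kB targets were higher in 9 of 11 with 0 lower (9 adjusted over the list alone, median 0.77, 0.00049, and 0.14 with an estimated correlation), with TRAF1 at 1.78 and RELB at 1.53. p53 targets had 11 higher and 3 lower of 18 (median 0.45, 0.03, and 0.56 with an estimated correlation), with BTG2 at 2.42, TP53INP1 at 1.70 and GADD45A at 1.19. This call was absent without DMSO replicate 3 (0.057). The integrated stress response list had 4 higher and 12 lower of 20 (median -0.48, 0.006, and 0.52 with an estimated correlation), with SLC7A11 at -2.43 and PHGDH at -1.45. T cell identity genes had 9 higher and 15 lower of 29 (median -0.38, 0.026, and 0.56 with an estimated correlation), and cBAF subunits 15 higher and 2 lower of 20 (median 0.23, 0.011, and 0.35 with an estimated correlation). Of B cell markers 2 genes could be tested and both were lower (median -1.76, 0.011, and 0.095 with an estimated correlation). The T cell identity call was absent after median-ratio rescaling (0.055), with CD1E at -3.57 and RAG1 at -2.32.

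**Figure D2:**
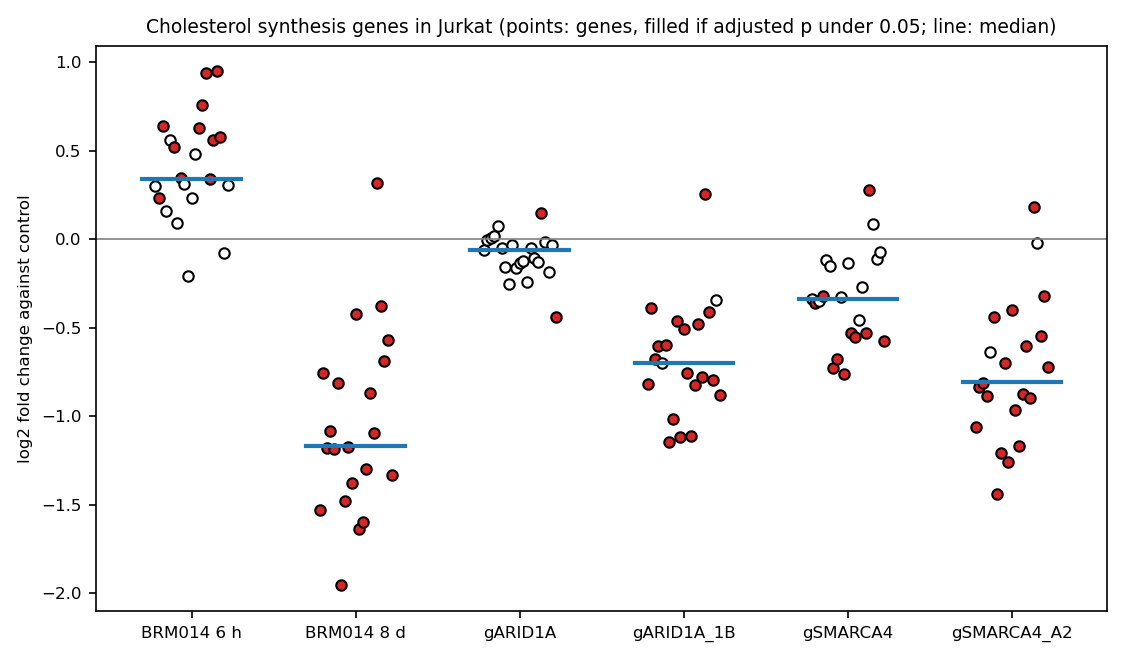
Log2 fold change against control (vertical axis) of each gene of the cholesterol synthesis list in the 6 Jurkat comparisons; points are genes, filled at an adjusted p under 0.05, and the line is the list median. The median was 0.34 after BRM014 at 6 h, -1.17 at 8 d, -0.06 in gARID1A, -0.70 in gARID1A_1B, -0.34 in gSMARCA4 and -0.81 in gSMARCA4_A2.

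The effects at 8 d and 6 h were compared as a difference of log2 fold changes, which asked how the response moves with time. The difference was called in 7929 genes, 4606 with a higher and 3323 with a lower effect at 8 d. The tyrosine phosphatase gene PTPN6 fell by 2.30 at 6 h and was higher by 1.88 at 8 d, a difference of 4.17 (adjusted p = 4.2e-12). TAL1 turned from -0.42 to 1.26 (difference 1.68 ± 0.11, adjusted p = 8e-11), NOTCH1 from -0.78 to 0.33 (1.11 ± 0.13, 3.5e-07) and GATA3 from -0.73 to 0.32 (1.05 ± 0.18, 6.3e-05). The cholesterol synthesis list turned from higher to lower, with a median difference of -1.48 and all 21 members called lower (21 adjusted over the list alone, camera adjusted p = 6.8e-13, and 0.30 with an estimated correlation). The cell cycle list also had a lower effect at 8 d, in 25 of 31 members with 0 higher (27 and 1 adjusted over the list alone, median -0.40, 1.4e-11, and 0.082 with an estimated correlation). T-ALL transcription factors had a higher effect at 8 d in 19 of 25 and a lower one in 3 (19 and 4 adjusted over the list alone, median 0.53, 8.8e-05, and 0.30 with an estimated correlation). Ribosomal proteins passed downward (-0.22), and NF-kB targets (0.59), immediate early genes (0.55), NOTCH1 targets (0.34), T cell identity (0.45), p53 targets (0.34), interferon response (0.40) and cBAF subunits (0.14) upward, with adjusted p of 0.17 to 0.42 under an estimated correlation. The 6 h and 8 d controls were separate DMSO groups, so this difference carries any difference between culture times.

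Guides against ARID1A alone asked what follows when this cBAF-specific subunit is targeted. TCF7 fell from 14.1 ± 0.44 TPM in gAAVS1 to 1.72 ± 0.14 TPM (-2.47 ± 0.08, adjusted p = 3e-15). NINJ2, a cell adhesion gene (chromosome 12, 564296 to 663445), rose from 5.01 ± 0.187 to 42.4 ± 1.58 TPM (2.85 ± 0.10, adjusted p = 7e-15), and ARHGAP29 (2.46) and CCR4 (1.75) rose. CD79A (-2.53), TARP (-1.91), DTX1 (-1.85), KLF2 (-1.75), RAG1 (-1.48) and NOTCH3 (-1.35) fell. MYC rose by 0.53 and TAL1 by 0.38. In all, 3748 genes were called, 1385 higher and 2363 lower, with 32 and 104 by at least 2-fold, and the split was 1919 and 2023 after median-ratio rescaling. MYC and ribosome biogenesis genes (4 higher and 0 lower of 28, or 3 and 0 adjusted over the list alone, median 0.12, adjusted p = 0.00024), cytosolic ribosomal proteins (5 and 0 of 28, or 6 and 0 adjusted over the list alone, 0.07, 0.00072) and interferon response genes (8 and 2 of 19, 0.01, 0.013) passed camera. The cell cycle list did so with 0 higher and 6 lower of 31 (0 and 11 adjusted over the list alone, -0.14, 0.025), a call that median-ratio rescaling ended (0.12). Each of these 4 lists had an adjusted p = 0.83 with an estimated correlation.

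Guides against ARID1A and ARID1B asked what happens when both alternative ARID1 subunits are targeted. SOCS1, an inhibitor of cytokine signalling (chromosome 16, 11254417 to 11256204), rose from 1.36 ± 0.363 to 110 ± 9.69 TPM (5.57 ± 0.22, adjusted p = 7.6e-14). NSMF (3.04), IFIT3 (2.63), FBP1 (2.50) and the pro-apoptotic BMF (2.38) rose. CXCR4 fell from 215 ± 12.5 to 24.7 ± 1.77 TPM (-3.07 ± 0.11, adjusted p = 9.9e-15), and PLA2G3 (-2.97), RCBTB2 (-2.85), CD79A (-2.64), FXYD2 (-2.63) and KLF2 (-2.59) fell. TCF7 (-2.08), DTX1 (-2.34), NOTCH3 (-1.51), MYB (-0.90) and BCL2 (-0.64) fell, and TAL1 was not called (-0.07). In all, 7182 genes were called, 3046 higher and 4136 lower, and 153 and 241 by at least 2-fold, a split that limma-voom on recovered reads turned to 4153 and 3616. Cholesterol synthesis genes were lower in 18 of 21 and higher in 1 (20 and 1 adjusted over the list alone, median -0.70, adjusted p = 5e-05, and 0.86 with an estimated correlation). Interferon response genes were higher in 11 of 19 and lower in 2 (13 and 2 adjusted over the list alone, 0.27, 0.00019, and 0.34 with an estimated correlation), with IFIT2 at 1.32 and SAMD9L at 1.23. Cell cycle genes were lower in 19 of 31 with 0 higher (19 adjusted over the list alone, -0.17, 0.0003, and 0.80 with an estimated correlation). Ribosomal proteins had 3 higher and 0 lower of 28 (0.07, 0.025, and 0.86 with an estimated correlation), a call absent without gARID1A_1B replicate 3 (0.16). T cell identity genes had 5 higher and 17 lower of 29 (5 and 19 adjusted over the list alone, -0.30), not called at 0.056 and called at 0.037 after median-ratio rescaling.

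Set against gARID1A directly, gARID1A_1B asked how the 2 groups differ. ARID1B was lower (-0.85), and ARID1A was higher (0.28, adjusted p = 0.00016, 101 ± 5.07 against 83.1 ± 3.38 TPM), so changes here cannot be assigned to the guide against ARID1B alone. SOCS1 was higher by 4.56 ± 0.22 (110 ± 9.69 against 3.78 ± 1.12 TPM, adjusted p = 8.3e-12), and BMF (2.69), FBP1 (2.37) and HEY1 (2.05) were higher. PLA2G3 (-2.32), PI16 (-2.03), RCBTB2 (-1.62) and MYB (-0.82) were lower. Of 3749 genes called, 1854 were higher and 1895 lower, and 2740 and 1415 with the mitochondrial genes left out. The lower count was 1205 without gARID1A_1B replicate 3. Cholesterol synthesis genes were lower in 16 of 21 and higher in 0 (20 and 1 adjusted over the list alone, median -0.62, adjusted p = 1e-08, and 0.60 with an estimated correlation). Interferon response genes had 10 higher and 2 lower of 19 (the same adjusted over the list alone, 0.21, 0.00074, and 0.43 with an estimated correlation). Camera also passed the mitochondrially encoded mRNAs (5 higher and 0 lower of 13, 0.15, 0.0016), whose share of TPM was 24.1 ± 1.22% in gARID1A_1B and 21.9 ± 0.907% in gARID1A. The p53 list (5 and 0 of 18, 0.13, 0.0056) and histones (3 and 0 of 11, 0.26, 0.017) passed upward. The MYC and ribosome biogenesis list (0 and 5 of 28, -0.16, 0.0023), glycolysis (1 and 7 of 22, -0.12, 0.0026), cell cycle (0 and 5 of 31, -0.07, 0.0083), TAL1-complex targets (1 and 7 of 15, -0.26, 0.015) and the stress response (0 and 4 of 20, -0.22, 0.023) passed downward. With an estimated correlation these 8 lists had adjusted p of 0.43 to 0.73. Without gARID1A replicate 1 the TAL1-complex and stress response calls were absent (0.087 and 0.37), and without gARID1A_1B replicate 1 the cell cycle call (0.061).

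Guides against SMARCA4 asked what follows when this ATPase is targeted. ARHGAP29, a regulator of the actin cytoskeleton (chromosome 1, 94168905 to 94314592), rose from 6.41 ± 0.521 to 62.1 ± 2.8 TPM (3.09 ± 0.10, adjusted p = 2.4e-15), and EEF1A2 (2.59) and APOL3 (2.57) rose. PLA2G3 (-3.30), TRAT1 (-2.70), the recombinase genes RAG2 (-2.69) and RAG1 (-1.69), CD1E (-2.66) and TCF7 (-2.04) fell. TAL1 rose by 0.64, GATA3 by 0.64, NOTCH1 by 0.34 and ETS1 by 1.22, and MYC fell by 0.24, the last not called without gSMARCA4 replicate 3 (-0.18) or without gAAVS1 replicate 1 (-0.20). In all, 7338 genes were called, 4507 higher and 2831 lower, with 241 and 175 by at least 2-fold, and the split was 3833 and 3652 after median-ratio rescaling. T cell identity genes had 5 higher and 19 lower of 29 (6 and 19 adjusted over the list alone, median -0.33, adjusted p = 4.9e-06, and 0.23 with an estimated correlation). Interferon response genes had 13 higher and 1 lower of 19 (the same adjusted over the list alone, 0.53, 4.9e-06, and 0.057 with an estimated correlation), with IFIT3 at 1.77 and IFI44 at -1.19. Cell cycle (1 and 15 of 31, -0.15, 0.00014) and glycolysis (1 and 10 of 22, -0.14, 0.00041) were lower, both with 0.23 under an estimated correlation. Cholesterol synthesis had 1 higher and 9 lower of 21 (-0.34, 0.0029, and 0.70 with an estimated correlation). NF-kB targets had 6 higher and 0 lower of 11 (0.29, 0.015, and 0.30 with an estimated correlation), and histones 6 and 0 of 11 (0.63, 0.036, and 0.23 with an estimated correlation). The histone call was absent without gAAVS1 replicate 1 (0.058). Of B cell markers 2 genes could be tested and both fell (-1.51, 0.0048, and 0.057 with an estimated correlation), CD79A by 2.36.

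Guides against SMARCA4 and SMARCA2 asked the same of both ATPases, though SMARCA2 mRNA was not lower in this group. SOSTDC1, a secreted inhibitor of BMP and WNT signalling (chromosome 7, 16461481 to 16465738), rose from 24.5 ± 3.22 to 364 ± 17.2 TPM (3.85 ± 0.11, adjusted p = 2e-16). EEF1A2 (3.71), DBNDD1 (3.37), CD38 (3.17), CTTN (2.91) and FOXB1 (2.88) rose, and PLA2G3 (-3.48), TRAT1 (-2.89), CD1E (-2.88), CXCR4 (-2.70) and RCBTB2 (-2.30) fell. TAL1 rose by 1.28, GATA3 by 1.05 and HHEX by 2.11, while MYC fell by 0.94 and NOTCH3 fell by 1 on the log2 scale. In all, 11130 genes were called, 7337 higher and 3793 lower, and 753 and 233 by at least 2-fold. Median-ratio rescaling moved the median of all genes by -0.11 in this comparison, from 0.11, and gave 5479 higher and 5617 lower, so a small increase here is relative to the scaling. The cBAF and PBAF and ncBAF subunit lists, not called, turned from 0.12 to -0.01 with it.

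In gSMARCA4_A2 the cell cycle list kept its call with an estimated correlation (0 higher and 29 lower of 31, or 30 lower adjusted over the list alone, median -0.49, adjusted p = 3.1e-16, and 0.018 with an estimated correlation), with CDC6 at -1.05, MCM2 at -0.70 and CCNA2 at -0.67. Glycolysis and hypoxia genes also did (1 and 18 of 22, or 1 and 19 adjusted over the list alone, -0.38, 1.7e-07, and 0.041 with an estimated correlation), with VEGFA at -1.30. The lists of MYC and ribosome biogenesis (1 and 22 of 28, -0.33, 2e-07), cholesterol synthesis (1 and 18 of 21, -0.81, 2.6e-07) and ribosomal proteins (3 and 13 of 28, -0.08, 0.00056) were lower, each with 0.48 under an estimated correlation. T cell identity genes had 5 higher and 17 lower of 29 (the same adjusted over the list alone, -0.35, 1.9e-05, and 0.25 with an estimated correlation). p53 targets had 14 higher and 1 lower of 18 (14 and 2 adjusted over the list alone, 0.54, 0.011, and 0.48 with an estimated correlation), with TP53INP1 at 1.97, BTG2 at 1.33 and BBC3 at 1.01. NF-kB targets had 9 higher and 0 lower of 11 (0.55, 0.0019, and 0.21 with an estimated correlation). Replication-dependent histones had 9 higher and 0 lower of 11 (9 adjusted over the list alone, 1.54, 0.00062, and 0.054 with an estimated correlation), with H2AC6 at 2.64. Histone mRNAs mostly lack a poly(A) tail, and this group also had more genes above 0, 27267 ± 206 against 25683 ± 420 in gAAVS1. The 2 B cell markers tested were lower (-1.40, 0.015, and 0.08 with an estimated correlation), a call that median-ratio rescaling ended. Apoptosis regulators, not called, had a median of -0.01 and a mean of 0.13.

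Set against gSMARCA4 directly, gSMARCA4_A2 asked how these 2 groups differ. TRIB1 was higher by 2.14 ± 0.12 (adjusted p = 3.9e-11), H2AC6 by 1.82 and SOSTDC1 by 1.67, and GIMAP5 (-1.42), CD28 (-1.37) and MYC (-0.70) were lower. SMARCA2 was lower against gSMARCA4 (-0.24, adjusted p = 0.012), and SMARCA4 was higher (0.17, adjusted p = 0.024, 49.9 ± 2.35 against 44.2 ± 1.63 TPM), the latter not called after median-ratio rescaling (0.09) or without gSMARCA4_A2 replicate 1 (0.14), its replicate 3 (0.17) or gSMARCA4 replicate 2 (0.14). In all, 6953 genes were called, 4751 higher and 2202 lower, or 3172 and 3746 after median-ratio rescaling. The cell cycle list was lower in 27 of 31 with 0 higher (28 adjusted over the list alone, -0.37, 3.5e-23, and 0.0031 with an estimated correlation), glycolysis in 10 of 22 with 0 higher (12 adjusted over the list alone, -0.21, 1e-06, and 0.048 with an estimated correlation), and histones were higher in 9 of 11 with 0 lower (1.03, 4.7e-05, and 0.027 with an estimated correlation). Lists of MYC and ribosome biogenesis (0 and 21 of 28, -0.27, 8e-12), cholesterol synthesis (0 and 12 of 21, -0.44, 4.1e-07), ribosomal proteins (1 and 12 of 28, -0.09, 3.1e-06) and interferon response (4 and 12 of 19, -0.35, 4.7e-05) were lower, with 0.31, 0.45, 0.39 and 0.081 under an estimated correlation. p53 targets (10 and 0 of 18, 0.24) and NF-kB targets (8 and 0 of 11, 0.37) were higher at 0.0086 each, with 0.48 and 0.31 under an estimated correlation. TAL1-complex targets (0.10) and heat shock genes (-0.28) passed at 0.029 each and had 0.57 with an estimated correlation.

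**Figure D3:**
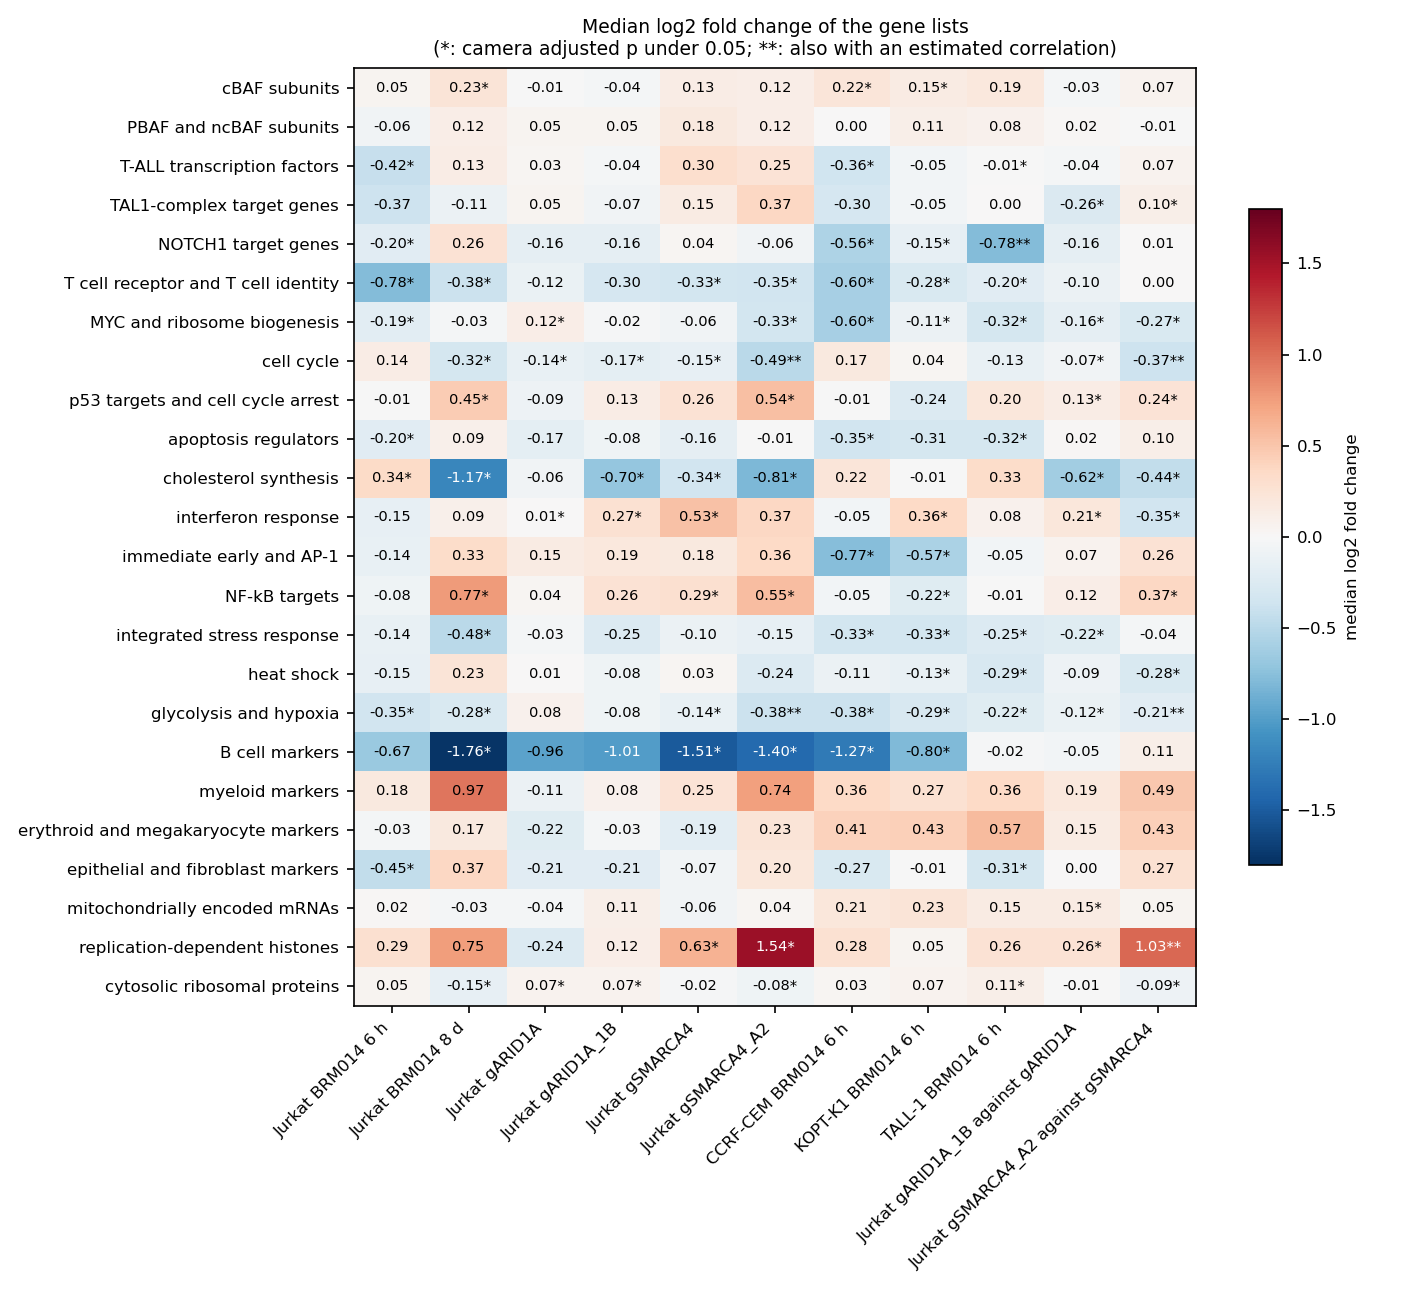
Median log2 fold change of the 24 gene lists (vertical axis) in the 11 comparisons (horizontal axis); colour and printed value give the median, and marks give camera calls. The cell cycle list had -0.49 in gSMARCA4_A2 and kept its call with an estimated correlation; the subunit lists turned from 0.12 to -0.01 in that column after median-ratio rescaling.

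BRM014 for 6 h in 3 further lines asked how far the Jurkat response is shared. In CCRF-CEM, NKX2-5, a homeobox gene (chromosome 5, 173232109 to 173235206), fell from 307 ± 27.8 to 17.8 ± 1.29 TPM (-4.03 ± 0.07, adjusted p = 1.9e-14), and CTTN rose from 0.944 ± 0.359 to 37.5 ± 6.31 TPM (4.31 ± 0.14, adjusted p = 2.1e-11). MYC fell from 193 ± 29.4 to 26.2 ± 2.62 TPM (-2.83), HES1 by 2.77, BCL11B by 2.47, GATA3 by 1.27 and NOTCH1 by 1.32, while TAL1 rose by 0.96. Of 16241 genes tested 8092 were called, 4694 higher and 3398 lower, with 270 and 575 by at least 2-fold, and 3617 and 4220 after median-ratio rescaling. MYC and ribosome biogenesis genes were lower in 22 of 28 with 0 higher (22 adjusted over the list alone, median -0.60, adjusted p = 7.9e-11, and 0.28 with an estimated correlation), with ODC1 at -1.83. Immediate early genes were lower in 12 of 16 with 0 higher (12 adjusted over the list alone, -0.77, 4.2e-06, and 0.14 with an estimated correlation), with JUN at -2.66. T cell identity (5 and 18 of 32, -0.60, 8.1e-05), NOTCH1 targets (2 and 8 of 17, -0.56, 0.00055) and B cell markers (0 and 2 of 4, -1.27, 0.019) were lower, each with 0.14 under an estimated correlation. Glycolysis (1 and 13 of 23, -0.38, 0.00022), the stress response (1 and 10 of 20, -0.33, 0.001), T-ALL transcription factors (7 and 14 of 23, -0.36, 0.0071) and apoptosis regulators (4 and 9 of 14, -0.35, 0.04) were lower, with 0.28, 0.28, 0.31 and 0.40 under an estimated correlation. cBAF subunits had 12 higher and 2 lower of 20 (0.22, 0.033, and 0.28 with an estimated correlation). Median-ratio rescaling ended the apoptosis and cBAF calls (0.061 and 0.071), as did leaving out DMSO replicate 3 (0.087) and BRM014 replicate 3 (0.055). Without BRM014 replicate 3 the cholesterol list, otherwise not called, passed at 0.011 with a median of 0.74.

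In KOPT-K1, OSM, a cytokine gene (chromosome 22, 30262829 to 30266851), fell from 51.8 ± 9.19 to 1.6 ± 0.565 TPM (-4.35 ± 0.15, adjusted p = 7.3e-11), and SYT11 (3.13), CTTN (2.65) and SYP (2.48) rose. NOTCH3 fell by 2.84, the NOTCH target DTX1 by 2.32 and NOTCH1 by 1.42, MYC was not called (0.01, adjusted p = 0.97) and MYB rose by 0.81. In all, 6187 genes were called, 3721 higher and 2466 lower, with 199 and 375 by at least 2-fold, and 2757 and 3297 after median-ratio rescaling. Immediate early genes were lower in 11 of 16 with 0 higher (11 adjusted over the list alone, -0.57, 0.0009, and 0.28 with an estimated correlation), and glycolysis genes in 11 of 23 with 0 higher (11 adjusted over the list alone, -0.29, 0.0009, and 0.34 with an estimated correlation). Interferon response genes were higher in 12 of 22 and lower in 5 (13 and 5 adjusted over the list alone, 0.36, 0.036, and 0.45 with an estimated correlation), with OAS1 at 1.59 and IFIT3 at 1.31. B cell markers (0 and 4 of 4, -0.80, 0.0019), T cell identity (7 and 17 of 32, -0.28, 0.0022), the stress response (1 and 8 of 20, -0.33, 0.003), NOTCH1 targets (3 and 8 of 17, -0.15, 0.0087) and cBAF subunits (11 and 1 of 20, 0.15, 0.016) passed camera, with 0.069, 0.28, 0.34, 0.26 and 0.28 under an estimated correlation. MYC and ribosome biogenesis (1 and 7 of 28, -0.11), NF-kB targets (3 and 7 of 13, -0.22) and heat shock genes (0 and 4 of 12, -0.13) passed at 0.036 each and had 0.61, 0.34 and 0.54 with an estimated correlation. Without DMSO replicate 1 the first of these was not called (0.26), without BRM014 replicate 2 the interferon list was not (0.05 as rounded), and median-ratio rescaling ended the other 2 (0.07 and 0.056).

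In TALL-1, NOTCH1 itself fell from 150 ± 5.66 to 11 ± 1.14 TPM (-3.66 ± 0.09, adjusted p = 8.9e-13), with DTX1 at -3.12 and NOTCH3 at -2.32. CHD4, the remodelling ATPase of the NuRD complex (chromosome 12, 6570082 to 6607379), fell from 233 ± 9.11 to 14.9 ± 1.52 TPM (-3.88 ± 0.24), CD300A from 387 ± 27 to 21 ± 1.58 TPM (-4.14) and TMC8 by 4.22, and the antiproliferative gene BTG2 rose from 31.5 ± 2.01 to 290 ± 23.2 TPM (3.16 ± 0.08, adjusted p = 9.7e-13). GATA3 fell by 1.61, MYC by 1.55 and BCL2 by 1.10, while MYB rose by 1.00. In all, 7461 genes were called, 4324 higher and 3137 lower, with 380 and 611 by at least 2-fold. NOTCH1 target genes had 2 higher and 10 lower of 17 (the same adjusted over the list alone, median -0.78) and kept their call with an estimated correlation (adjusted p = 3.5e-05, and 0.04 with an estimated correlation). In every comparison this list includes NOTCH1 itself, NOTCH3, DTX1 and MYC, so its call is not separate from their changes. Genes of MYC and ribosome biogenesis were lower in 22 of 28 with 0 higher (23 adjusted over the list alone, -0.32, 1.9e-06, and 0.48 with an estimated correlation). Glycolysis (2 and 11 of 23, -0.22, 0.013) and heat shock (0 and 6 of 12, -0.29, 0.013) were lower. T-ALL transcription factors passed camera at 0.018 with 4 higher, 10 lower and 9 not called of 23, a median of -0.01 and a mean of -0.42, so the call rests on some members. T cell identity (-0.20), apoptosis regulators (-0.32), the stress response (-0.25), epithelial markers (-0.31) and, upward, ribosomal proteins (0.11) passed at 0.049 each. With an estimated correlation these 8 lists had 0.48, or 0.61 for ribosomal proteins, and median-ratio rescaling ended the last 5 calls (0.074 to 0.34).

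Across the 15069 genes tested in all 4 lines, 1581 were called higher and 919 lower in every line at 6 h, against 86 and 20 if the lines were independent. The last 2 numbers also assume that every gene has the same chance of a call, so they are no test of a shared response. At least 2-fold in every line were 25 and 42. SASH3 fell by a similar amount in each (-2.87 to -2.57), and TMC8 (-4.22 to -1.40), CD6, KCNA6, CXCR4 and CHD4 (-3.88 to -0.82) also fell in all. SYT11 (1.27 to 3.29), CTTN (1.39 to 4.31), CCDC121, ZNF341, TRIB1 (0.73 to 3.01) and SYP rose in all. Correlations of log2 fold changes, which are across genes, and genes are not independent replicates, had Pearson's r of 0.68 (Spearman's coefficient 0.69) between Jurkat and CCRF-CEM, 0.59 (0.58) between Jurkat and KOPT-K1 and 0.58 (0.58) between Jurkat and TALL-1. Among the other lines r was 0.56 to 0.61. NOTCH3 fell in all 9 comparisons with a control, with log2 fold changes between -2.84 and -1, whereas MYB and TAL1 went both ways. RUNX1 fell by 0.32 in Jurkat at 6 h and was higher by 0.40 in KOPT-K1.

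**Figure D4:**
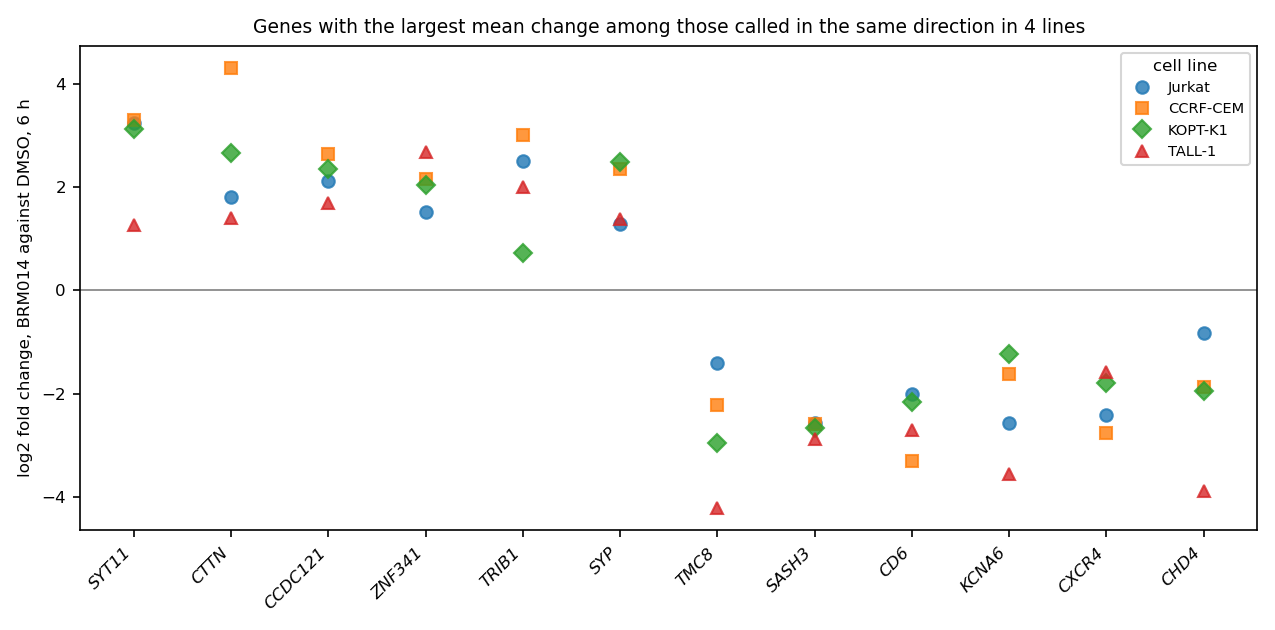
Log2 fold change of BRM014 against DMSO at 6 h (vertical axis) of the 6 protein-coding genes with the largest mean rise and the 6 with the largest mean fall, among those called in the same direction in 4 lines. Each point is 1 line. SASH3 lay between -2.87 and -2.57, and CHD4 between -3.88 and -0.82.

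**Figure D5:**
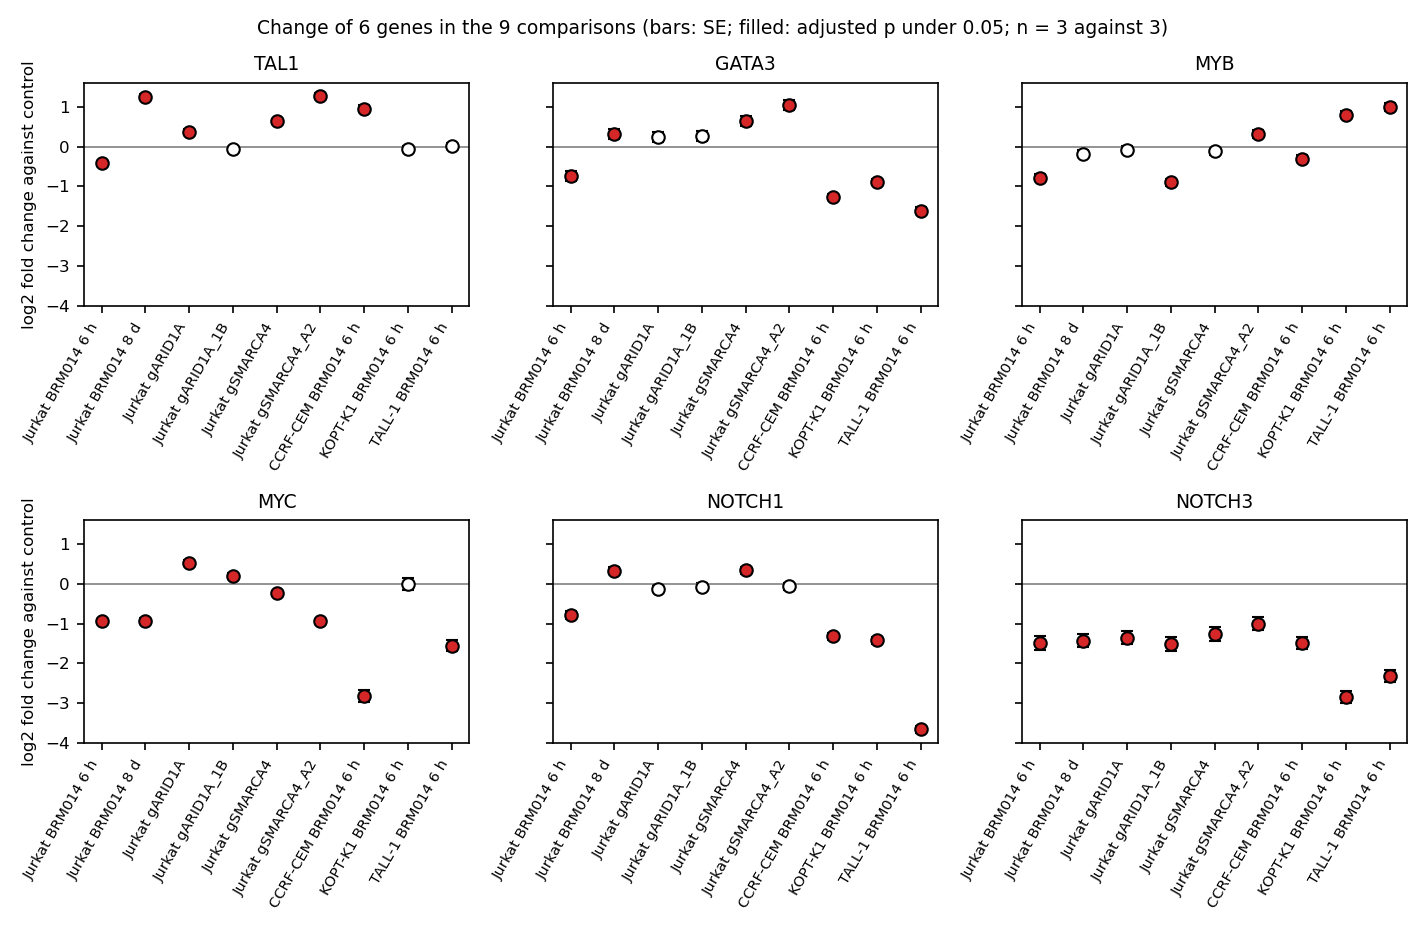
Log2 fold change against control (vertical axis) of TAL1, GATA3, MYB, MYC, NOTCH1 and NOTCH3 in the 9 comparisons; bars are SE and filled points have an adjusted p under 0.05. NOTCH3 lay between -2.84 and -1, and TAL1 between -0.42 and 1.28.

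Differences between lines in the effect of BRM014 were tested directly. KOPT-K1 and CCRF-CEM differed in 2978 genes, TALL-1 and CCRF-CEM in 3311, and TALL-1 and KOPT-K1 in 3472. MYC and ribosome biogenesis genes fell less in KOPT-K1 than in CCRF-CEM (18 of 28 called, or 22 adjusted over the list alone, median difference 0.47, 6.4e-12, and 0.50 with an estimated correlation), and interferon response genes had a higher effect there (10 of 22, or 14 with 2 lower adjusted over the list alone, 0.41, 1.1e-05, and 0.26 with an estimated correlation). Immediate early genes had a higher effect in TALL-1 than in CCRF-CEM (9 of 16, or 11 adjusted over the list alone, 0.68, 6.1e-05, and 0.40 with an estimated correlation). NOTCH1 targets fell more in TALL-1 than in KOPT-K1 (8 of 17 with 3 the other way, or 8 and 4 adjusted over the list alone, -0.44, 0.0019, and 0.18 with an estimated correlation). MYB rose in KOPT-K1 and TALL-1 and fell by 0.30 in CCRF-CEM, with differences of 1.11 ± 0.12 (1.4e-05) and 1.31 ± 0.12 (2.2e-06). The fall in CCRF-CEM was not called without its replicate 3 in both groups (-0.17). Jurkat was in the other table, made with another library kit, so its differences from these lines were not tested.

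Finally, the effects of BRM014 and of the guides were set side by side in Jurkat, which asked whether the inhibitor and the guides act alike. BRM014 at 8 d and gSMARCA4_A2, which share no control, had r = 0.79 (Spearman's 0.77) across 17936 genes, with 5314 genes higher in both (2705 if independent), 2800 lower in both (873 if independent) and 208 opposite. With gSMARCA4 r was 0.69, with gARID1A_1B 0.56 and with gARID1A 0.33. Numbers given as independent assume that every gene has the same chance of a call, and so are no test of a shared response. BRM014 at 6 h had r = 0.41 with gSMARCA4_A2, 0.39 with gSMARCA4, 0.29 with gARID1A_1B, 0.16 with gARID1A (856 genes opposite) and 0.40 with BRM014 at 8 d, where 1471 genes called in both went opposite ways. Guide groups share gAAVS1, which alone gave r = 0.50 in simulations of unchanged genes, beside 0.71 for gARID1A and gARID1A_1B, 0.80 for gSMARCA4 and gSMARCA4_A2 and 0.64 for gARID1A_1B and gSMARCA4_A2. Simulated effects held noise alone, so 0.50 is no baseline for the r of effects that also hold real changes. The pair of gARID1A and gSMARCA4_A2 had 0.39, with 716 genes opposite, gARID1A and gSMARCA4 0.52 and gARID1A_1B and gSMARCA4 0.62. The covariances of these 6 pairs in the order given were 0.0675, 0.144, 0.116, 0.0497, 0.0489 and 0.0836, against at most 0.0104 in the 20 simulations, which gave 0 genes called in both.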

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

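Of the tests in this part, those that weigh explanations for cholesterol genes, detected genes, histone mRNAs and zinc finger genes were chosen after these patterns were seen, and the comparison of cholesterol genes with the guide groups and the reading of zinc finger genes outside Jurkat were written after their results were known. Single genes and the cholesterol list below drew attention because the effect of BRM014 differed between 2 times or between 2 lines by a direct test of the difference. Detected genes and histones in gSMARCA4_A2 and zinc finger genes were noticed in the tables and are no difference between times or lines.

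Between 8 d and 6 h in Jurkat 7929 genes differed. The largest higher effects at 8 d were in EEF1A2 (4.66, adjusted p = 7.9e-14), CTHRC1 (4.29, 1.3e-11) and PTPN6 (4.17, 4.2e-12), and the largest lower effects in FXYD2 (-3.27, 1.3e-07), FXYD6-FXYD2 (-2.71, 1.5e-07), which shares reads with it, and TRAT1 (-2.63, 1.8e-12). PTPN6 stood at 33.1 ± 2.14 TPM in the 8 d DMSO group and 113 ± 22.4 TPM in the 6 h DMSO group, so its controls differed too. Opposite directions were called in ARID1B (difference 0.55, adjusted p = 8.3e-06), TAL1 (1.68), GATA3 (1.05) and NOTCH1 (1.11). ARID1B fell by 0.15 at 6 h, a call absent without BRM014 replicate 1 (adjusted p = 0.1), BRM014 replicate 3 (0.16) or any 1 DMSO library (0.066 to 0.092), and GATA3 at 8 d lost its call after rescaling.

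Between KOPT-K1 and CCRF-CEM 2978 genes differed, with the largest values in NKX2-5 (4.03, adjusted p = 3.1e-12), RGS16 (3.54, 2e-08) and BHLHE23 (3.47, 2e-06) and, lower in KOPT-K1, OSM (-2.98, 1.8e-07), SCEL (-2.98, 4.2e-09) and MAL (-2.50, 3.1e-06). MYB went opposite ways (1.11). Between TALL-1 and CCRF-CEM 3311 genes differed, with NKX2-5 (4.05, 2.9e-12), KCNK17 (3.70, 8.5e-09) and RGS16 (3.42, 8.5e-09), and lower in TALL-1, ACP5 (-3.69, 2.9e-09), RASAL1 (-3.23, 2.1e-09) and MMP9 (-2.93, 4e-07). MYB again went opposite ways (1.31). Between TALL-1 and KOPT-K1 3472 genes differed, with OSM (4.35, 3.8e-09), BTG2 (3.25, 1.9e-10) and KRT83 (3.10, 8.9e-09), and lower in TALL-1, ACP5 (-3.56, 4.7e-09) and PLEKHG1 (-2.79, 1.3e-09), the last not called by limma-voom (-2.04). Most of these genes were near 0 TPM in the DMSO group of the line without the change, where a decrease could not show. NKX2-5 stood at 307 ± 27.8 TPM in CCRF-CEM, 0.0164 TPM in KOPT-K1 and 0 TPM in TALL-1, OSM at 51.8 ± 9.19 TPM in KOPT-K1, 2.37 TPM in CCRF-CEM and 0 TPM in TALL-1, and ACP5 at 151 ± 20.9 TPM in TALL-1 and 0.0187 and 0.0205 TPM in the other 2. MYB and BTG2 were transcribed in both lines compared, MYB at 279 ± 9.34 TPM in KOPT-K1, 281 ± 11.8 TPM in CCRF-CEM and 171 ± 16.7 TPM in TALL-1, and BTG2 at 31.5 ± 2.01 TPM in TALL-1 and 6.86 ± 0.725 TPM in KOPT-K1. KRT83 was near 0 TPM in both DMSO groups (0.0963 and 0 TPM) and rose in TALL-1.

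The cholesterol synthesis list had a median difference of -1.48 between 8 d and 6 h. Without DMSO 8 d replicate 1, which stood apart from its group, it was -1.51 (camera adjusted p = 2.4e-12), and after median-ratio rescaling -1.52 (1e-11), which argues against that library or the scaling as the cause. The list call itself was absent with an estimated correlation (adjusted p = 0.30). The BRM014 groups alone lay apart by -0.95 ± 0.11 (median and its standard error), which argues against the controls as the whole cause. The DMSO groups moved by 0.55 ± 0.1 the other way and so may have contributed. Members of this list move together (estimated correlation 0.811), so the error of a median over its genes can understate the spread between libraries. The list was also lower in gSMARCA4, gSMARCA4_A2 and gARID1A_1B, with -0.34 as the highest median of the 3 (adjusted p = 0.70, 0.48 and 0.86 with an estimated correlation), but not in gARID1A (-0.06, adjusted p = 0.71), so loss of cBAF function over days remains a candidate explanation that 1 of the 4 guide groups did not show. All guide groups share the gAAVS1 libraries, in which HMGCS1 stood at 418 ± 129 TPM, so they are not separate support for it. SMARCA4 and SMARCA2 are also ATPases of related complexes, so the guides against them do not single out cBAF. Cell density and serum or medium age at 8 d are not given in the sources used here and stay open.

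Libraries of gSMARCA4_A2 had more genes above 0 than those of the 8 other Jurkat groups, and their histone mRNAs were higher. After every library was thinned to 29.7 M reads, the lowest gSMARCA4_A2 library still lay 549 genes above the highest other (26298 and 25749), which argues against depth. Carried-over genomic DNA may contribute to the detected genes, since 402 olfactory receptor genes had 33.3 ± 1.73 reads per 1e+06 against 21.4 ± 1.14 in gAAVS1, a ratio of 1.56, and it stays open beside wider transcription in this group, which was not tested. The rise was not limited to this group. BRM014 at 8 d had 29.5 to 30.2 against 17.3 to 21.5 in its DMSO group, while gARID1A had 21 to 22.1. For the histones, the median TPM increase of 6.89 was 88.9 times the mean olfactory receptor level of 0.0776 TPM, and the list median was 1.42 after rescaling, which argues against genomic DNA and scaling. Carry-over of RNA without poly(A) stays open, because 26 listed RNAs without poly(A) had a median of 0.11 ± 0.1, below the bound set for excluding it, but that list left out the 17 5S and 5 5.8S ribosomal RNA genes, which were all called higher (medians 1.77 and 2.13). The 18S and 28S genes, also outside that list, had medians of 0.57 and 0.65 and none was called.

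Zinc finger genes with a ZNF symbol, 352 in number, were more often higher than lower after BRM014 at 6 h, with 121 and 53 called in Jurkat, 167 and 44 in CCRF-CEM, 134 and 25 in KOPT-K1 and 164 and 45 in TALL-1. Against 10000 random sets matched for length and level, the median lay at percentile 99.08 in Jurkat and 100 in the 3 other lines. After median-ratio rescaling the lowest median was 0.06 with a standard error of 0.021, in Jurkat, and the others were 0.106 ± 0.025 in CCRF-CEM, 0.085 ± 0.022 in KOPT-K1 and 0.138 ± 0.027 in TALL-1. In those 3 lines the median lay above every matched set and stayed positive after rescaling, a reading written after the results were known. In Jurkat it did not lie above every matched set. Random sets and these standard errors treat genes as independent, although zinc finger genes share reads. They also give no spread between libraries, so they cannot decide the question. Gene length with level and the scaling were therefore not excluded as causes in any line, and no biological explanation was tested.

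Other splits of the libraries were counted for each number of called genes. The 10 splits of 3 against 3 are too few for a share under 0.05, and in each of the 11 comparisons 1 split, the real one, gave as many genes. Every other split mixes treated and control libraries, which puts the effect into the spread within groups. Low counts in those splits were therefore fixed in advance, and the contrast with the real count is no evidence against chance. The highest other split called 4 genes for Jurkat at 6 h (8509 real), 0 at 8 d (10739), 0 in gARID1A (3748), 0 in gARID1A_1B (7182), 0 in gSMARCA4 (7338) and 1 in gSMARCA4_A2 (11130). It called 13 for CCRF-CEM (8092), where splits that part all 3 pairs called 0, 2 for KOPT-K1 (6187), 3 for TALL-1 (7461), 1 for gARID1A_1B against gARID1A (3749) and 1 for gSMARCA4_A2 against gSMARCA4 (6953). For differences between effects, 2 of 100 splits gave as many genes for 8 d and 6 h (highest other 8027), 4 for KOPT-K1 and CCRF-CEM (5386), 6 for TALL-1 and CCRF-CEM (4396) and 4 for TALL-1 and KOPT-K1 (4792), a share under 0.05 in each but the third. Splits that keep 1 of the contrasts whole retain its effect, a structure of the samples, and the 81 splits that regroup both gave at most 0, 3, 4 and 3 genes. Those 81 remove both effects, so the splits cannot decide whether 2 effects differ by more than chance. For genes called in all 4 lines, 1 of 100 splits gave as many higher (1581) and 1 as many lower (919), with 0 in the highest other. A regrouped line called at most 13 genes, so a count near 0 was fixed in advance. These splits cannot decide whether sharing between lines exceeds chance.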

How the results depend on the processing

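Tests with limma-voom and those without CCRF-CEM replicate 3 in both groups were chosen after the data were seen. Depth limits little here, since 1 read on a gene of 1 kb equals 0.116 TPM in CCRF-CEM DMSO replicate 1, and the limits are 3 libraries per group and the fixed total of TPM. Of 857 values of named genes, 812 kept their side of the threshold after median-ratio rescaling (36 weaker, 9 stronger), 850 with a pseudocount of 0.1, 839 without a filter, 835 without mitochondrial genes (7 weaker, 1 stronger, the rest without a value because those genes are left out), 851 without trend, 808 with only the compared groups, 820 with a replicate block and 841 with limma-voom. No value called in either of the 2 fits compared turned direction. Direction was not compared where neither fit called the gene. With 1 library left out 5022 values were kept, 260 were weaker and 4 stronger. Of 360 list results, an estimated correlation left 239 on their side of the threshold and ended 121 calls. Most of the 239 were called in neither test. The only calls it kept were cell cycle and glycolysis in gSMARCA4_A2, these and histones in gSMARCA4_A2 against gSMARCA4, and NOTCH1 targets in TALL-1. Fry left 256 on their side and gave 90 more calls, median-ratio rescaling left 340 and a replicate block 324. These numbers too include lists called in neither fit. Among list results called by camera or fry, 3 had opposite directions in the 2 tests, with medians of -0.06 for PBAF and ncBAF subunits in Jurkat at 6 h, -0.01 for apoptosis regulators in gSMARCA4_A2 and -0.01 for NF-kB targets in TALL-1. The cause was not tested.

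With a change of at least 2-fold also required, fewer genes pass by construction. The counts were 370 for BRM014 in Jurkat at 6 h, 1105 at 8 d, 136 in gARID1A, 394 in gARID1A_1B, 416 in gSMARCA4, 986 in gSMARCA4_A2, 845 in CCRF-CEM, 574 in KOPT-K1 and 991 in TALL-1. They were 120 for gARID1A_1B against gARID1A, 179 for gSMARCA4_A2 against gSMARCA4, 985 for 8 d and 6 h, 429 for KOPT-K1 and CCRF-CEM, 623 for TALL-1 and CCRF-CEM and 561 for TALL-1 and KOPT-K1.

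ARID1A in gARID1A_1B was called higher after median-ratio rescaling (0.13), without mitochondrial genes (0.13) and with limma-voom (0.15), and ranged from 0.07 to 0.14 with 1 library left out, called at 0.14 without gARID1A_1B replicate 3. The cause was not tested.

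Correlations of effects moved with the settings below. With a pseudocount of 0.1 and with a filter of 5 TPM they were 0.35 and 0.42 for Jurkat 6 h and 8 d, 0.35 and 0.43 for 6 h and gSMARCA4_A2, 0.25 and 0.30 for 6 h and gARID1A_1B, 0.73 and 0.82 for 8 d and gSMARCA4_A2, 0.62 and 0.75 for 8 d and gSMARCA4, and 0.50 and 0.58 for 8 d and gARID1A_1B. They were 0.61 and 0.74 for Jurkat and CCRF-CEM, 0.51 and 0.65 for Jurkat and KOPT-K1, 0.49 and 0.64 for Jurkat and TALL-1, 0.52 and 0.66 for CCRF-CEM and KOPT-K1, 0.52 and 0.64 for CCRF-CEM and TALL-1 and 0.47 and 0.61 for KOPT-K1 and TALL-1. Without a filter they were 0.28 for 6 h and gARID1A_1B, 0.77 for 8 d and gSMARCA4_A2, 0.67 for 8 d and gSMARCA4, 0.54 for 8 d and gARID1A_1B, and in the order of the lines above 0.63, 0.53, 0.52, 0.59, 0.58 and 0.55. Without mitochondrial genes they were 0.69 for 8 d and gSMARCA4 and 0.55 for 8 d and gARID1A_1B. With 1 library left out they ranged from 0.36 to 0.41 for 6 h and 8 d, 0.37 to 0.43 for 6 h and gSMARCA4_A2, 0.27 to 0.29 for 6 h and gARID1A_1B, 0.76 to 0.80 for 8 d and gSMARCA4_A2, 0.67 to 0.69 for 8 d and gSMARCA4 and 0.54 to 0.56 for 8 d and gARID1A_1B. For the lines the ranges were 0.66 to 0.68, 0.57 to 0.59, 0.56 to 0.58, 0.58 to 0.61, 0.57 to 0.59 and 0.55 to 0.56. The cause was not tested.

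With 1 library left out the number of called genes was 7697 to 7810 for Jurkat at 6 h, 9871 to 10696 at 8 d, 2709 to 3410 in gARID1A, 6081 to 6458 in gARID1A_1B, 6297 to 6573 in gSMARCA4, 10162 to 10620 in gSMARCA4_A2, 7110 to 7895 in CCRF-CEM, 5234 to 5520 in KOPT-K1 and 6654 to 6821 in TALL-1. For differences between effects it was 7330 to 8136 for 8 d and 6 h, 2320 to 3325 for KOPT-K1 and CCRF-CEM, 2779 to 3508 for TALL-1 and CCRF-CEM and 2911 to 3163 for TALL-1 and KOPT-K1. It was 2746 to 3238 for gARID1A_1B against gARID1A and 5287 to 6314 for gSMARCA4_A2 against gSMARCA4. Without CCRF-CEM replicate 3 in both groups 7906 genes were called there, and 3507 for the difference between KOPT-K1 and CCRF-CEM and 3548 for that between TALL-1 and CCRF-CEM.

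Pairing passed the threshold in CCRF-CEM alone and was not excluded elsewhere. With a replicate block, which the main fit left out, 8397 genes were called in CCRF-CEM instead of 8092. The counts were 8573 at 6 h and 7402 at 8 d in Jurkat, 3981 in gARID1A, 7785 in gARID1A_1B, 7324 in gSMARCA4, 11743 in gSMARCA4_A2, 7472 in KOPT-K1 and 8362 in TALL-1. The number of genes lower at 8 d was 2704 with the block and 4127 without it.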

Other observations

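Values below are given without a test or an explanation, and were picked after they were seen. Some genes of the Jurkat response to BRM014 lay further from control at 8 d than at 6 h, and others did not. PLA2G3 fell by 3.02 at 6 h and fell by 4.82 at 8 d, CD6 went from -2.01 to -3.78 and TRAT1 from -1.48 to -4.11, while BTG2 was higher by 1.31 and by 2.42. TCF7 (-2.38 and -1.99), MYC (-0.94 and -0.93) and NOTCH3 (-1.49 and -1.43) did not lie further from control at 8 d. Guide groups shared several of the genes of BRM014 at 8 d, among them TRAT1 (-2.70 in gSMARCA4, -2.89 in gSMARCA4_A2), EEF1A2 (2.59 and 3.71) and SOSTDC1 (3.85 in gSMARCA4_A2, 3.41 at 8 d).

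Among libraries that stood apart from their group were DMSO 8 d replicate 1, BRM014 8 d replicate 2, replicate 2 of both 6 h groups and replicate 1 of gARID1A and of gSMARCA4_A2 in Jurkat, and replicate 3 of both groups in CCRF-CEM and in TALL-1. Olfactory receptor genes had 29.5 to 30.2 reads per 1e+06 in BRM014 at 8 d and 17.3 to 21.5 in its DMSO group. Of ribosomal RNA genes in gSMARCA4_A2, those of 18S (0.57) and 28S (0.65) were not called in any of 5 copies each.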
